A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

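RNA from chemostat cultures of Saccharomyces cerevisiae had been hybridised to 14 Affymetrix GeneChip yeast arrays, 1 per culture. The deposited value of each probe set is a signal intensity on a linear scale. Per the labels the authors used GCOS 2.1. The labels do not name the summary method or the background correction. In the deposited values the mean after removal of the lowest and highest 2% of probe sets lay between 150.1 and 150.15 on every array. The deposited array description files, of unit "other", hold no expression measurement. 10 arrays had one, and they were read for scanner type, order of the run days and strain or medium as typed in. The description files of the 4 CEN.PK113-7D arrays in glucose and ethanol were not used here.

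Every array was scaled again to a trimmed mean of 150, signals under 12 were set to 12, and log2 was taken. Of 9335 probe sets, 60 are controls, and 7075 of the other 9275 exceeded 12 on at least 3 of the 14 arrays and were tested. The annotation names 1 gene for 6504 probe sets and several genes for 328, and 2443 probe sets that are not controls have no annotation. Genes are given by symbol, the main ones with their systematic name. Positions are those of the R64 reference annotation. For gene lists each gene was represented by the probe set with the highest mean log2 signal, which gave 5300 genes.

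The arrays form 4 groups: CEN.PK113-7D in glucose (n = 4), Orange01 in glucose (n = 3), CEN.PK113-7D in glucose and ethanol (n = 4) and Orange02 in glucose and ethanol (n = 3). A linear model with the 4 group means was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal. It had 10 residual degrees of freedom and 5.33 prior degrees of freedom. The comparisons were each Orange strain against CEN.PK113-7D in its medium, CEN.PK113-7D between the media, and the difference between the strain effects. All tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over the 7075 probe sets of each comparison, with a threshold of 0.05. SE is the moderated standard error of the log2 change. Mean signals are arithmetic means of the scaled signals before the floor. A log2 change next to a group at 12 is a lower bound. The number of arrays limits the precision.

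The 38 gene lists were written from general knowledge of yeast, with the subject of the series known. They cover carotenoid-related topics such as drug resistance and isoprenoid synthesis as well as general metabolism and stress. A list was tested with limma's camera (inter-gene correlation 0.01) if at least 3 members were measured, and p was adjusted over the 38 lists. Camera sets a list against all other genes. Each list was tested again with the correlation estimated from the data (statmod 1.5.0 served the random-effect fits) and with fry, which asks whether members move one way or, in its mixed form, either way. Counts of members past the threshold are given over all probe sets and adjusted over the list alone.

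Groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each strain comparison, up to 8 risers and 8 fallers with the largest changes, past the threshold and without overlap between the arrays of the groups, and 5 of each for the medium and for the difference. It adds up to 6 members past the threshold from the drug resistance, mevalonate, marker and mating lists and 3 from any other list that passed. It always gives 8 genes: HMG1, URA3, PDR5, SNQ2, PDR3, ERG9, BTS1 and ERG20. Genes outside it are said to have been chosen after their values were seen.

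The procedure was tested on simulated data with the same groups and 7075 probe sets, with 50 probe sets changed at each fold size. For Orange01 it found 25 of 50 at 1.5-fold and 43 at 2-fold. For Orange02 it found 15 and 40, for the medium 25 and 41, and for the difference 4 and 18. Of the calls, 9 of 173, 8 of 161, 6 of 169 and 2 of 110 were false. Both changed lists, each of 20 members shifted by 1 on the log2 scale, were found in each comparison, with 1 unchanged list called for Orange02. Smaller list shifts, such as the −0.344 of the ribosomal protein list in Orange01, were not simulated. These rates are therefore not taken to hold for smaller shifts, for lists with correlated members or for probe sets near the floor.

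Alternatives covered quantile normalization, median scaling, the deposited values unscaled, a floor of 30, a pseudocount of 16, no filter, a filter at 30, fits of the compared groups alone, moderation without the trend or in its robust form, array weights, replicate number or run day as a block, a 2-fold minimum, other representatives of a gene, other list tests and leaving out each array in turn. Leaving out the array labelled Orange01 replicate 2 alone was thus planned for Orange01 and for the difference. Its use as a second fit for all values, also for Orange02 and the media, was added after the data were seen, as were fits without it with quantile normalization and together with CEN.PK113-7D glucose replicate 4. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.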

Results

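Transcript levels were measured in aerobic, carbon-limited chemostat cultures of the yeast Saccharomyces cerevisiae. CEN.PK113-7D, a laboratory strain, was grown on glucose (4 arrays) and on glucose with ethanol (4 arrays). Strain Orange01 was grown in the first medium (3 arrays) and strain Orange02 in the second (3 arrays). The series is about yeast that makes carotenoids, coloured isoprenoids foreign to this species, and about how this affects the cells. The genotypes of both Orange strains were not used here. Feeds held 7.5 g/L glucose, with 9.38 mM ethanol added in the second medium, at a dilution rate of 0.1 per hour, pH 5 and 30 °C. The ethanol sentence in the labels of both glucose and ethanol groups names Orange02 alone, and was taken to cover CEN.PK113-7D. Between 26.4% and 29.9% of the probe sets of an array had signals under 12, and median signals ran from 41.3 to 52.6. The number of arrays limits the precision of all values below.

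The array labelled Orange01 replicate 2 carried transcripts of growth on galactose. GAL1, GAL2, GAL7 and GAL10, genes of galactose uptake and use, gave signals of 1370, 3389, 1523 and 1509, and no other array exceeded 7.99, 14.1, 10.7 and 23.1. HXT6, a high-affinity hexose transporter, gave 495.5 against 2442 to 4543 on the other 13 arrays. BTS1, the geranylgeranyl diphosphate synthase, gave 26.6 on this array, 562.2 and 644.4 on the other Orange01 arrays, and 19.4 to 25.8 on the 4 CEN.PK113-7D glucose arrays. The description file of that array names CEN.PK113-7D and galactose. Orange01 values are from all arrays of the group unless stated. Counts of calls and the values of several genes, BTS1 among them, are therefore also given without this array. The use of the fit without it for these values, and the galactose genes and HXT6, were chosen after the values were seen.

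**Figure D1:**
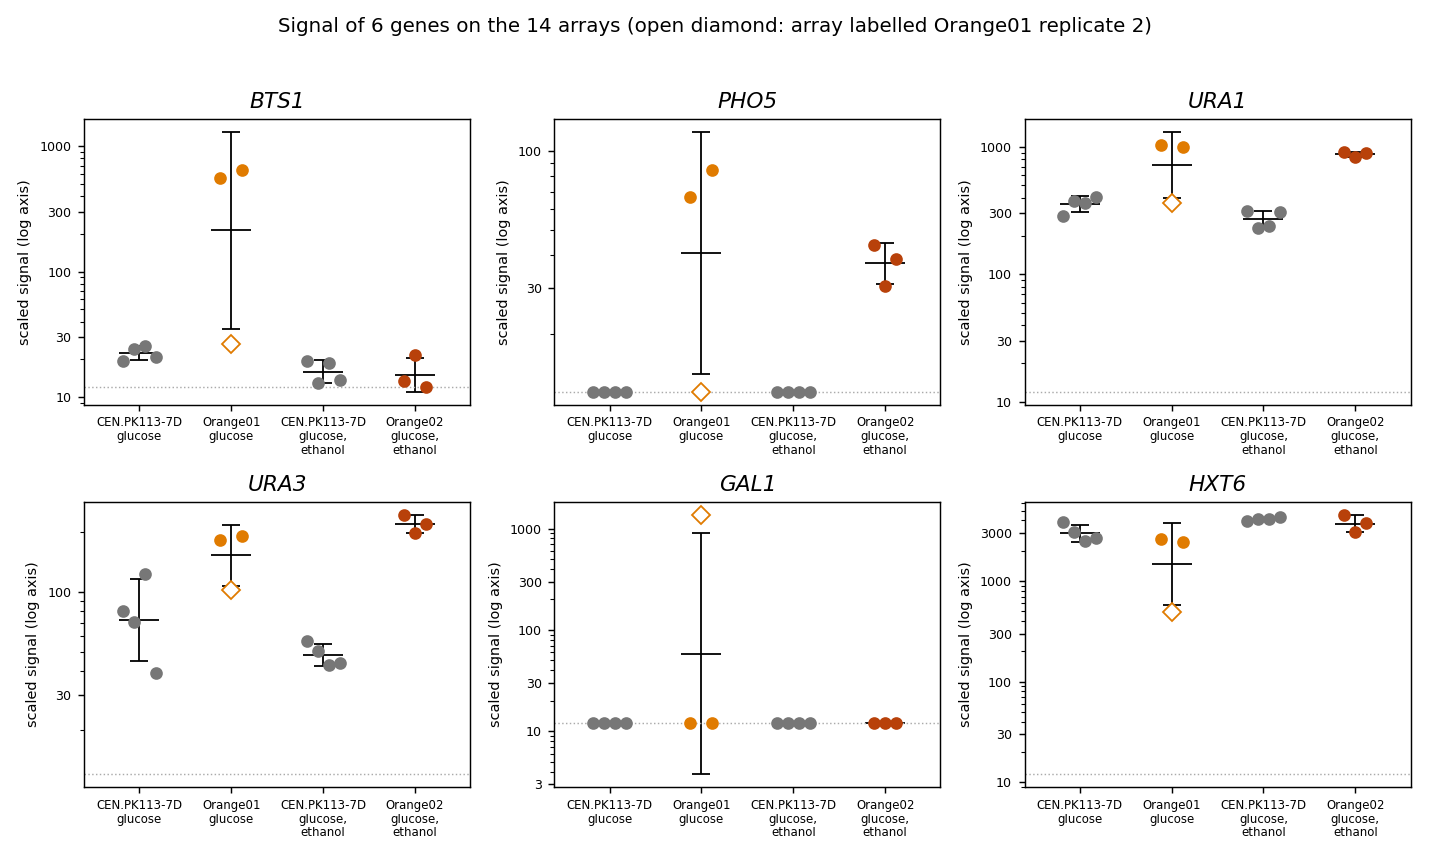
Scaled signal (log axis) of BTS1, PHO5, URA1, URA3, GAL1 and HXT6 on the 14 arrays by group, with signals under 12 drawn at 12, the dotted line; horizontal lines are means of log2 signals and bars 1 SD. The array labelled Orange01 replicate 2 (open diamond) lies at 26.6 for BTS1 and at 1370 for GAL1.

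Orange01 was compared with CEN.PK113-7D in glucose to ask what differs in a carotenoid strain. BTS1 (YPL069C, chromosome XVI, 422885 to 423892), which makes the precursor of carotenoids, rose 26.8-fold without the array labelled Orange01 replicate 2 (log2 change 4.75, SE 0.25, n = 2 and 4, adjusted p = 1.08e-07). With all 3 Orange01 arrays its change was 9.48-fold and did not pass (log2 3.25, SE 0.75, adjusted p = 0.0786). Without that array PHO5, a secreted acid phosphatase, rose at least 6.26-fold (log2 2.65, SE 0.16, adjusted p = 3.53e-07) and URA1, the dihydroorotate dehydrogenase of pyrimidine synthesis, 2.85-fold (log2 1.51, SE 0.17, adjusted p = 0.000404). With it neither passed, with adjusted p of 0.105 and 0.119. PHO3, another acid phosphatase, fell by 1.30 on the log2 scale (adjusted p = 0.0168) and THI7, a thiamine transporter, by 0.92 (adjusted p = 0.0324) without that array. With all 3 Orange01 arrays neither PHO3 nor THI7 passed. PHO5, URA1, PHO3 and THI7 were chosen after their values were seen.

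With all 3 Orange01 arrays, 29 of 7075 probe sets passed, 26 higher and 3 lower, and 10 of them changed at least 2-fold. Of the 29, 17 name 1 gene and 11 have no annotation. Without the array labelled Orange01 replicate 2 there were 28, 23 higher and 5 lower, of which 15 and 2 were shared with the 29. Named risers in both fits were CPD1, a cyclic nucleotide phosphodiesterase (at least 3.51-fold, log2 SE 0.24, n = 3 and 4, adjusted p = 0.00257), PDR5, a multidrug efflux pump (on 1 of its probe sets, 2.76-fold, SE 0.25, adjusted p = 0.0174), and HEM3, an enzyme of haem synthesis (2.19-fold, SE 0.17, adjusted p = 0.0063). CPS1, a vacuolar carboxypeptidase, rose 2.18-fold, CBP2, needed to splice a mitochondrial intron, 2.01-fold, the transfer RNA gene SUF6 2.24-fold, PSP2 at least 2.05-fold and the ribosomal RNA gene RDN18-1 at least 2.61-fold. YGR018C fell by at least 0.85 on the log2 scale (SE 0.12, adjusted p = 0.00309). The array labelled Orange01 replicate 2 was placed by its share of the log2 change from CEN.PK113-7D to the other Orange01 arrays. It lay at 115% for CPD1, 146% for RDN18-1, 91.3% for PDR5, 90.6% for PSP2 and 89.8% for HEM3. CPS1 (66.7%), CBP2 (50.6%) and SUF6 (25.6%) lay lower, as did BTS1 (5.15%). As that array shares the scanner type of the other Orange01 arrays, these shares do not tell scanner from strain. Its description file names CEN.PK113-7D. If that is right, the high shares of CPD1, RDN18-1, PDR5, PSP2 and HEM3 go against a strain effect. The brightest PDR5 probe set did not pass (log2 0.72, SE 0.18, adjusted p = 0.0995), and passed without CEN.PK113-7D glucose replicate 4 (log2 0.82, adjusted p = 0.0432). In CEN.PK113-7D the risers had mean signals of 8.19 for RDN18-1 to 20.4 for CPS1, near the floor of 12. CPD1, PSP2 and RDN18-1 were under 12 on 3 of the 4 CEN.PK113-7D arrays and HEM3, SUF6 and PDR5 on 1, replicate 4. With the floor at 12 these folds are therefore lower bounds, but they depend on the processing. Over the alternatives the log2 change ran from 0.023 to 1.205 for HEM3, 0.233 to 1.635 for RDN18-1 and 0.327 to 1.547 for SUF6. It ran from 0.610 to 1.942 for CPD1, 0.750 to 1.066 for PSP2 and 0.843 to 1.679 for PDR5. For CBP2 and CPS1 it ran from 0.029 to 1.259 and from 0.544 to 1.268. The 18S ribosomal RNA controls gave 241 to 300.4 on Orange01 arrays and 25.02 to 206.6 on CEN.PK113-7D glucose arrays, and the 3′ to 5′ ratio of ACT1 was 1.5 to 1.77 and 1.74 to 2.6. The 25.02 and the 2.6 are from CEN.PK113-7D replicate 4. It was run on another day than replicates 1 to 3, whose 18S signals were 138.2 to 206.6.

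Genes of the isoprenoid route other than BTS1 gave small changes in Orange01. HMG1, the reductase of the mevalonate route, gave log2 −0.16 (adjusted p = 0.642), ERG20, the farnesyl diphosphate synthase, −0.37 (0.202) and ERG9, the squalene synthase, 0.04 (0.973). Of the 12 measured mevalonate genes none passed over all probe sets and 1 was higher when adjusted over the list alone. That list had mean 0.32 and median 0.02, while its test pointed lower (adjusted p = 0.999). URA3, a pyrimidine gene often used as a marker, gave log2 1.09 (SE 0.31, adjusted p = 0.128), and 1.38 (SE 0.32, adjusted p = 0.0878) without the array labelled Orange01 replicate 2. PDR3, a regulator of drug resistance, and SNQ2, an efflux pump, gave 0.15 and 0.21 (adjusted p = 0.857 and 0.957).

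The 29 calls moved with single arrays: 15 without CEN.PK113-7D glucose replicate 2, 54 without replicate 3, 69 without replicate 4, 19 without Orange01 replicate 1 and 7 without Orange01 replicate 3. CBP2 did not pass without CEN.PK113-7D replicate 1 or 2 or Orange01 replicate 1 or 3 (highest adjusted p = 0.189), SUF6 without those or CEN.PK113-7D replicate 3 (0.192), CPS1 without Orange01 replicate 1 or 3 (0.11), HEM3 without Orange01 replicate 3 (0.0523), and PDR5 without CEN.PK113-7D replicate 1 or Orange01 replicate 3 (0.112). URA3 passed without CEN.PK113-7D replicate 3 (0.0462). All 4 CEN.PK113-7D glucose arrays were read on one scanner type and all 3 Orange01 arrays on another, so scanner and strain cannot be told apart. Median scaling moved the median log2 change of all tested probe sets from 0.08 to −0.07, and 5 probe sets passed, 3 higher and 2 lower. After quantile normalization 12 passed, 8 higher and 4 lower.

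Ribosomal protein genes were lower in Orange01 as a group, with 74 of 80 below 0 and a mean log2 change of −0.25 (camera adjusted p = 2.98e-22). With an estimated correlation the adjusted p = 0.186, and after quantile normalization the call was lost. Lists of respiration (22 of 31 below 0, mean −0.11, adjusted p = 0.000203), the tricarboxylic acid cycle (13 of 16, −0.13, 0.00194), beta-oxidation (12 of 17, −0.15, 0.00194) and glycolysis (13 of 18, −0.08, 0.0151) were lower too. With an estimated correlation their adjusted p were 0.17, 0.135, 0.135 and 0.292. Fatty acid and phospholipid synthesis (12 of 19, −0.08, 0.0225), oxidative stress defence (15 of 27, −0.03, 0.0427), hexose transport (9 of 15, −0.27, 0.00777), genes of mating type a (6 of 7, −0.34, 0.0076), genes of mating type alpha (3 of 3, −0.34, 0.0225) and the seripauperin genes PAU (9 of 10, −0.32, 0.0076) completed the 11 lists. With an estimated correlation their adjusted p were 0.169, 0.307, 0.461, 0.292, 0.187 and 0.623, so none of the 11 held. No member of these lists passed over all probe sets. Adjusted over the list alone, 2 genes of mating type alpha and 1 PAU gene were lower and 1 glycolysis gene was higher. The mean log2 change of all genes was 0.17 in decile 3 of mean signal and −0.12 in decile 10.

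Without the array labelled Orange01 replicate 2, 8 lists were lower, among them ergosterol (adjusted p = 0.0248, and adjusted p = 0.219 with an estimated correlation), which is not one of the 11. With an estimated correlation 0 of the 8 passed in camera, in a fit with 885 probe sets at an unadjusted p under 0.05. Hexose transport (adjusted p = 0.733, shift −0.0175 against −0.361 with all arrays), mating type a (0.0683), mating type alpha (0.0648) and oxidative stress (0.0638) no longer passed then. Other arrays ended list calls as well. These were CEN.PK113-7D replicate 1 (fatty acid, 0.052), replicate 2 (mating type alpha, 0.102), replicate 3 (oxidative stress, 0.132) and replicate 4 (oxidative stress, 0.31, glycolysis, 0.0972, and PAU, 0.511, with a shift of −0.08 against −0.406). Leaving out Orange01 replicate 1 ended the calls of oxidative stress (0.131) and PAU (0.0584), and leaving out replicate 3 those of fatty acid (0.0942), mating type alpha (0.0906) and PAU (0.0942). The drug resistance, marker and haploid mating lists had adjusted p of 0.441, 0.319 and 0.763, with 3, 1 and 0 members higher adjusted over the list alone. In 14 of the 38 lists, none of them among the 11, median, mean and test differed in sign.

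Orange02 was compared with CEN.PK113-7D in glucose and ethanol with the same question. Genes of pleiotropic drug resistance, a set of efflux pumps and other proteins driven by Pdr1 and Pdr3, were higher as a group: all 19 measured lay above 0, with a mean log2 change of 0.76. PDR5 (YOR153W, chromosome XV, 619840 to 624375) rose 2.3-fold on its brightest probe set (log2 1.20, SE 0.18, n = 3 and 4, adjusted p = 0.0037), and all 6 of its probe sets that passed lay between 0.89 and 1.91. YGR035C rose at least 3.48-fold (log2 1.80, SE 0.11, adjusted p = 4.39e-07), PDR15, another efflux pump, 2.62-fold (log2 1.39, SE 0.19, adjusted p = 0.0029) and CIS1 2.07-fold (log2 1.05, SE 0.14, adjusted p = 0.00283). URA3 rose 4.59-fold (log2 2.20, SE 0.31, adjusted p = 0.0029) and URA1 3.24-fold (log2 1.70, SE 0.28, adjusted p = 0.0095).

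Of the 19 drug resistance genes, 4 passed over all probe sets and 11 were higher when adjusted over the list alone. The camera adjusted p was 2.57e-23, and with an estimated correlation the adjusted p was 0.000452. The subject of the series was known when this list was written. YOR1, a further pump, passed on a probe set that was not its brightest (log2 1.25, SE 0.23, adjusted p = 0.0242) but not on its brightest (0.92, adjusted p = 0.173), and was chosen after its values were seen. Another YOR1 probe set, under the floor of 12 in CEN.PK113-7D (5.7 to 11.2), gave 19.5 to 24.6 in Orange02. PDR3 gave 0.64 (adjusted p = 0.617). SNQ2 gave 1.75 (SE 0.88, adjusted p = 0.782), and 0.47 (adjusted p = 0.55) without CEN.PK113-7D glucose and ethanol replicate 2. BTS1 gave −0.08 (SE 0.75, and 0.22 when the array labelled Orange01 replicate 2 was left out of the shared variance, adjusted p = 1 in both), HMG1 −0.07 (0.999), ERG20 −0.35 (0.595) and ERG9 −0.05 (adjusted p = 1).

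**Figure D2:**
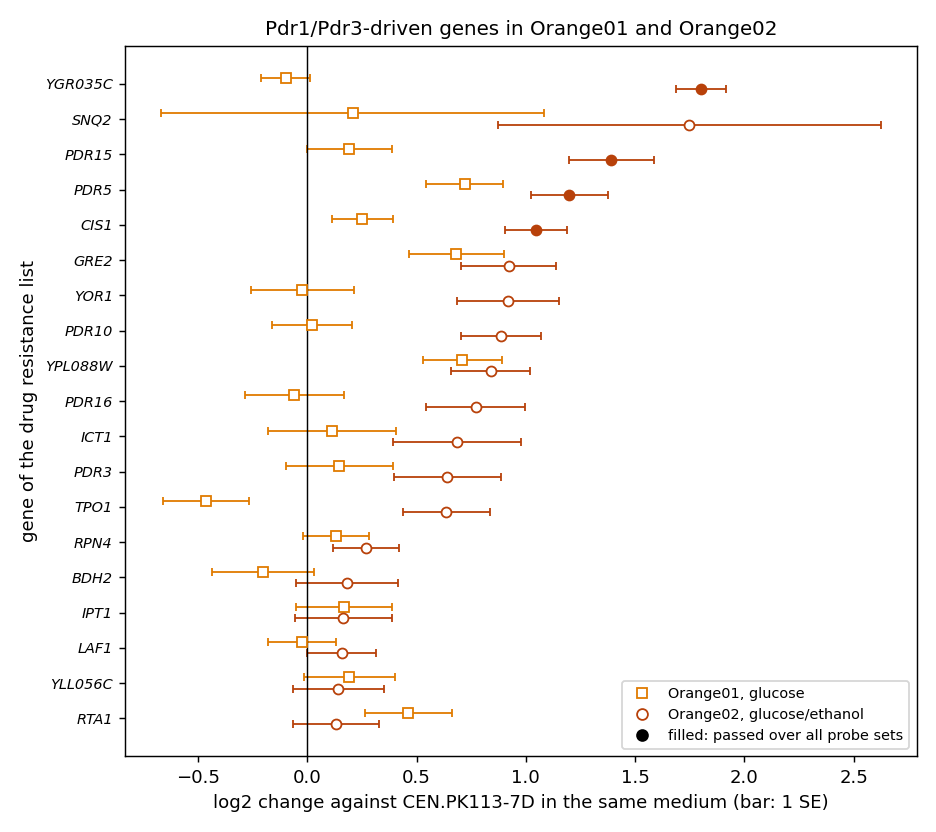
Log2 change (x axis) with its SE (bars) of the measured drug resistance genes in Orange01 and Orange02, each against CEN.PK113-7D in the same medium; filled points passed over all probe sets. All 19 genes lie above 0 in Orange02, and 13 do in Orange01.

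FET3, a multicopper oxidase of high-affinity iron uptake, fell by 2.70 on the log2 scale in Orange02 (6.5-fold, SE 0.37, n = 3 and 4, adjusted p = 0.00283). Its signals were 207 to 747.6 on the CEN.PK113-7D glucose and ethanol arrays and 43.4 to 73.6 in Orange02. In CEN.PK113-7D on glucose they were 67.4 to 119.3. A high level on those CEN.PK113-7D glucose and ethanol arrays would give both this fall and a rise between the media. SPS100, a spore wall gene, fell by 1.49 (SE 0.26, adjusted p = 0.0159), PAU4 by 1.32 and PAU10 by 1.28, the small nucleolar RNA gene SNR72 by 1.24, and HPF1, a mannoprotein gene, by 0.69 (SE 0.13, adjusted p = 0.0334). Of 16 iron genes 13 lay below 0 (mean log2 −0.70), 1 passed and 8 were lower adjusted over the list alone (camera adjusted p = 2.6e-10, with an estimated correlation adjusted p = 0.0791). The PAU genes, whose near-identical copies share probes, lay below 0 in 10 of 10 (mean −1.11, 2 passed, 7 adjusted over the list alone, adjusted p = 1.98e-14, with an estimated correlation adjusted p = 0.0791). Genes of amino acid synthesis driven by Gcn4 lay below 0 in 23 of 28 (mean −0.32, none passed, 4 adjusted over the list alone, adjusted p = 9.07e-11, with an estimated correlation adjusted p = 0.0791). The mean of that list was 0.34 between the media, where the same CEN.PK113-7D glucose and ethanol arrays entered.

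NAD and biotin synthesis genes lay below 0 in 9 of 12 (mean −0.31), with none past the threshold over all probe sets and, adjusted over the list alone, 6 lower and 1 higher. Their camera adjusted p was 3.08e-05, and 0.0133 with an estimated correlation. Ergosterol synthesis genes were lower as a group (13 of 16 below 0, mean −0.15, none passed, 3 adjusted over the list alone, adjusted p = 0.00124, with an estimated correlation adjusted p = 0.0791). Ribosomal protein genes lay below 0 in 62 of 80 (mean −0.12, none passed on either count, adjusted p = 9.87e-06, with an estimated correlation adjusted p = 0.639), a call lost after quantile normalization. Mevalonate genes (10 of 12 below 0, none on either count, adjusted p = 0.206) and the marker (1 passed, URA3, on both counts, 0.792), haploid mating (0.887), mating type a (0.972) and mating type alpha (0.204) lists did not pass. Median, mean and test differed in sign in 9 lists, none of which passed.

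In total 27 of 7075 probe sets passed, 13 higher and 14 lower, with 23 changed at least 2-fold. They are not as many genes: 19 of them name 1 gene, and these cover 7 genes higher and 6 lower. With a floor of 30 there were 12 higher and 3 lower, and with no filter 12 higher and 2 lower, and each shared 12 probe sets with the 27. There were 16 without CEN.PK113-7D glucose and ethanol replicate 3, 13 without Orange02 replicate 1 and 12 without Orange02 replicate 2. HPF1 did not pass without any 1 of the 7 arrays (highest adjusted p = 0.201), SNR72 without any but CEN.PK113-7D replicate 4 (0.295), PAU4 (0.161) and the PDR5 probe set with the largest change (0.108) without CEN.PK113-7D replicate 3 or 4 or any Orange02 array, SPS100 without CEN.PK113-7D replicate 2 or any Orange02 array (0.0893), and URA1 without Orange02 replicate 1 or 2 (0.069). When the array labelled Orange01 replicate 2 was left out of the shared variance estimate, PHO5 passed as well (at least 3.1-fold, log2 1.63, SE 0.14, adjusted p = 3.24e-05, against 0.24 with it). In that fit URA1, PHO5 and PDR5 were higher in both Orange strains, 3 shared probe sets where independent lists would share 0.0455. With all arrays 1 probe set was shared, where independent lists would share 0.0478. Both comparisons use the same variance estimate of a probe set, so their lists are not independent.

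**Figure D3:**
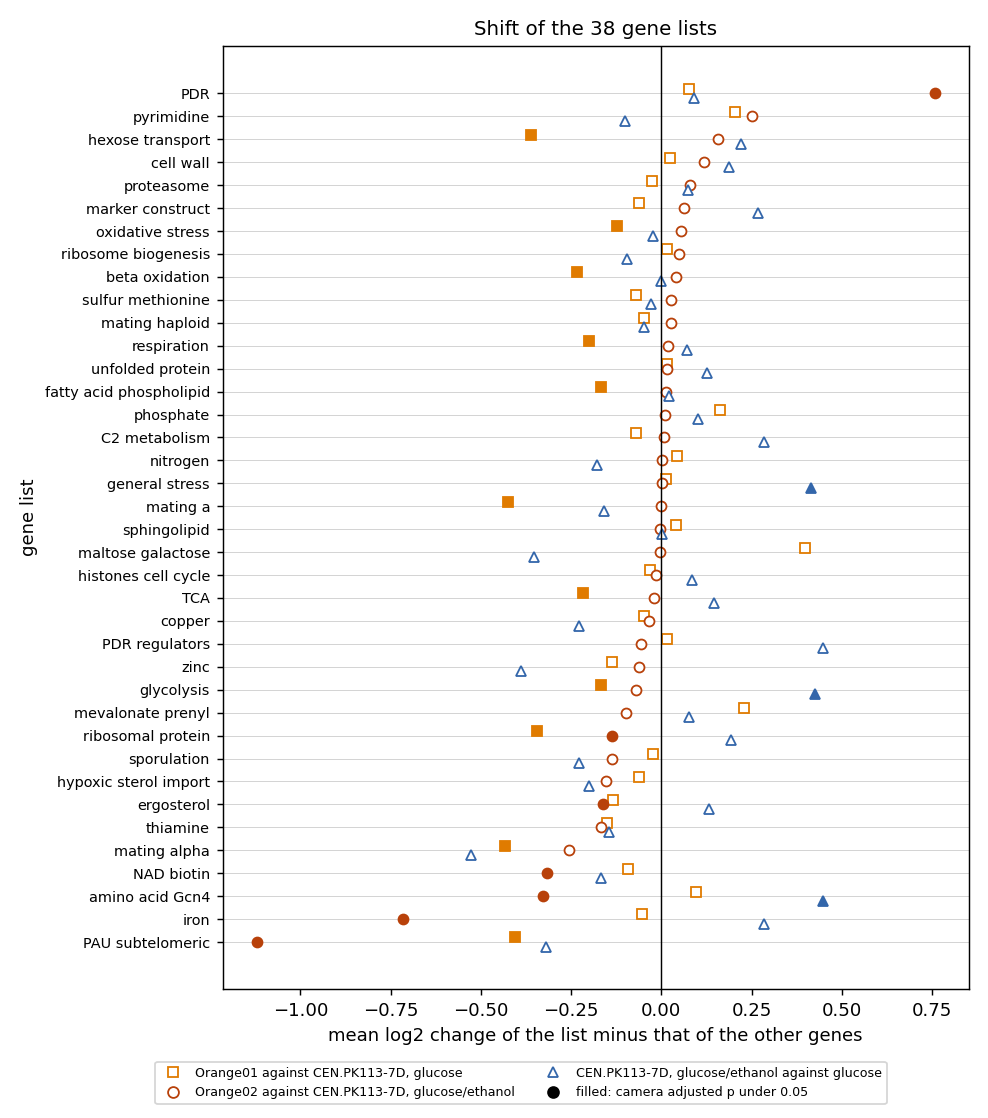
Mean log2 change of each of the 38 lists minus that of the other genes (x axis) in 3 comparisons; filled symbols have a camera adjusted p under 0.05. The drug resistance list in Orange02 lies farthest right, at 0.757, and the PAU list farthest left, at −1.12.

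CEN.PK113-7D was compared between the media. Genes of glycolysis and ethanol formation were higher with ethanol in the feed, as were genes of general stress and of amino acid synthesis driven by Gcn4. With an estimated correlation none of these 3 list calls held (adjusted p = 0.862 for each). Among their members CDC19, pyruvate kinase, rose 1.83-fold (log2 0.87, SE 0.16, n = 4 and 4, adjusted p = 0.000698), PDC1, pyruvate decarboxylase, 1.74-fold, TSL1, of trehalose synthesis, 1.84-fold, PGM2, phosphoglucomutase, 1.94-fold, and TRP2, of tryptophan synthesis, 2.16-fold (log2 1.11, SE 0.21, adjusted p = 0.000836). COX1 (Q0045), a mitochondrially encoded subunit of cytochrome oxidase, rose 56.4-fold (log2 5.82, SE 0.23, adjusted p = 5.91e-10). Another COX1 probe set, with its glucose group at the floor and chosen after its values were seen, did not pass (log2 at least 0.46, adjusted p = 0.0519). GPD2, a glycerol-3-phosphate dehydrogenase, fell by 2.20 on the log2 scale (SE 0.20, adjusted p = 3.19e-06). Medium and labelling protocol changed together in this comparison and cannot be told apart. The 3′ to 5′ ratio of ACT1 was 1.74 to 2.6 in glucose and 1.14 to 1.36 with ethanol, and the 18S ribosomal RNA controls had mean signals of 127.7 and 37.5. Glucose replicate 4 alone gave 25.02 for 18S, and the other glucose arrays 138.2 to 206.6.

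In the glycolysis list 17 of 18 lay above 0 and 8 passed, all higher, with ENO2, enolase, at 1.68-fold. For general stress 25 of 30 lay above 0, and 9 rose and 1 fell, with GAC1, of glycogen metabolism, at 1.93-fold. For Gcn4 23 of 28 lay above 0, and 12 rose and 1 fell, with LYS2 at 2.03-fold and ARG8 at 1.82-fold. Adjusted over the list alone these counts were 8 higher, 7 higher and 1 lower, and 12 higher and 1 lower. Camera adjusted p were 0.00481, 0.00572 and 0.0036, and 0.862 with an estimated correlation. After quantile normalization none of the 3 lists passed. Genes of growth on ethanol or acetate did not pass as a list (adjusted p = 0.125), with 10 members higher and 7 lower, or 12 and 8 adjusted over the list alone.

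The other large changes were in CPS1 (5.64-fold higher), NGK1 (at least 5.14-fold, with 3 of the 4 glucose arrays under 12), the fatty acid synthase gene FAS1 (4.74-fold and 4.79-fold on separate probe sets), YDL009C (log2 −2.80), SHU2 (−2.13), RSC8, of a chromatin remodelling complex (−2.06), and NTG1, a DNA glycosylase (−2.03). Other FAS1 probe sets moved less or the other way: the brightest rose 1.29-fold (log2 0.37, adjusted p = 0.0357) and another fell by 0.42 (adjusted p = 0.0469), both chosen after their values were seen. The first pair of FAS1 probe sets gave log2 1.43 and 0.91 without CEN.PK113-7D glucose replicate 4, against 2.25 and 2.26 with it, and the probe set at 2.26 did not pass without the array labelled Orange01 replicate 2 or any 1 of the 4 glucose and ethanol arrays (highest adjusted p = 0.0948). HMG1 rose 1.6-fold (SE 0.12, adjusted p = 0.000486), ERG13, of the mevalonate route, 1.3-fold, and RER2, of dolichol synthesis, fell by 0.44. In the drug resistance list PDR5 rose 1.95-fold, LAF1 1.97-fold, YLL056C 1.9-fold and GRE2 1.73-fold, while PDR16 fell by 1.59 and PDR3 by 0.75. That list had 5 members higher and 3 lower on both counts (adjusted p = 0.642, mean and median below 0, test higher). SAG1 and MF(ALPHA)1, both of mating type alpha, fell by 1.02 and 0.81.

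The marker list (adjusted p = 0.482) had LYS2, TDH3, ADH1 and HMG1 higher (TDH3 1.47-fold, ADH1 1.44-fold) and TRP1 lower (log2 −0.74), 4 and 1 on both counts. The mevalonate list (0.686) had 2 members higher and 1 lower, 2 and 0 adjusted over the list alone, and mating type alpha (0.518) had 2 lower on both counts. The mating type a (0.701) and haploid mating (0.701) lists did not pass either. URA3 (log2 −0.59, adjusted p = 0.109), BTS1 (−0.49, 0.599, and 0.0664 when the array labelled Orange01 replicate 2 was left out of the shared variance), ERG9 (−0.40, 0.165), ERG20 (0.08, 0.613) and SNQ2 (−0.74, 0.487) did not pass. SNQ2 passed without glucose and ethanol replicate 2 (log2 0.53, adjusted p = 0.0228) and URA3 without glucose replicate 4 (−0.88, 0.00688). In total 3000 of 7075 probe sets passed, 1211 higher and 1789 lower, with 306 and 441 at least 2-fold. Median scaling gave 1527 higher and 1376 lower, and quantile normalization 1450 and 1493. PDR3 did not pass without glucose replicate 1 or glucose and ethanol replicate 2 (highest adjusted p = 0.0541), ERG13 (0.0594) without glucose replicate 2 or glucose and ethanol replicate 3, TDH3 (0.0594) without replicate 3 of either, and RER2 (0.123) without glucose replicate 2 or 3 or glucose and ethanol replicate 1, 2 or 4. SHU2 gave −1.45 without glucose and ethanol replicate 2.

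The strain effects were then set against each other, Orange02 minus Orange01. YGR035C, of the drug resistance list, had the higher effect in Orange02 (log2 difference 1.90, SE 0.16, n = 14 arrays, adjusted p = 2.83e-05). CPD1 (−1.99, SE 0.34, adjusted p = 0.0307), UGA3, a regulator of GABA use (−1.49, SE 0.25, 0.0307), HEM3 (−1.41, SE 0.24, 0.0307), RDN18-1 (−1.39, SE 0.22, 0.0307) and PSP2 (−1.02, SE 0.14, 0.00604) had the lower. For RDN18-1 and PSP2 both glucose and ethanol groups lay at or near the floor, with an Orange02 effect set to 0 or 0.02 by it, so their difference restates the Orange01 effect with its sign turned. YGR035C lay near the floor in both glucose groups (9.99 to 13.99), so its difference largely restates its Orange02 effect of 1.80. Its lowest difference over the alternatives was 0.56, and its call was kept in each. The drug resistance list had the higher effect in Orange02 (16 of 19 above 0, mean 0.60, 1 passed, 6 adjusted over the list alone, camera adjusted p = 1.98e-11, and 0.00884 with an estimated correlation). BTS1 gave −3.33 (SE 1.06, adjusted p = 0.431) with all arrays and −4.83 (adjusted p = 4.24e-06) without the array labelled Orange01 replicate 2.

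These 6 probe sets were all that passed of 7075, 1 higher and 5 lower. With a floor of 30 there were also 6, but 5 higher and 1 lower, and 1 of them was shared, and with no filter there were 3 higher and 7 lower, of which 4 were shared. YGR035C signals were 41.9 to 46.3 on the Orange02 arrays and at most 14.5 on the others. PDR5 (0.48, adjusted p = 0.734), URA3 (1.11, 0.594), PDR3 (0.49), SNQ2 (1.54), HMG1 (0.09), ERG20 (0.03) and ERG9 (−0.09) did not pass. The SNQ2 difference was 0.26 (adjusted p = 0.9) without CEN.PK113-7D glucose and ethanol replicate 2. Strain, medium and labelling protocol differ together between the effects. Without the array labelled Orange01 replicate 2, CPD1 (0.0646), HEM3 (0.0578) and UGA3 (0.0578) did not pass. Leaving out single arrays ended the call of CPD1 for 11 of the 14 arrays (highest adjusted p = 0.159), of HEM3 for 12 (0.141), of UGA3 for 11 (0.109) and of RDN18-1 for 9 (0.103), and that of YGR035C for none. The count was 2 without CEN.PK113-7D glucose replicate 1, glucose and ethanol replicate 3, or Orange02 replicate 1 or 2. It was 3 without CEN.PK113-7D glucose replicate 4, Orange01 replicate 1 or 3, glucose and ethanol replicate 1 or 4, or Orange02 replicate 3.

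Of the 38 lists 13 differed between the strain effects, 9 higher in Orange02 and 4 lower. Ribosomal protein (adjusted p = 8.18e-06, with an estimated correlation adjusted p = 0.561), respiration (0.000258, then 0.152), hexose transport (0.000553, then 0.306) and beta-oxidation (0.00162, then 0.152) lists had the higher effect in Orange02. So had the tricarboxylic acid cycle (0.0187, then 0.152), oxidative stress (0.0218, then 0.273), mating type a (0.0237, then 0.366) and fatty acid (0.0291, then 0.152) lists. The Gcn4 (3.38e-09, then 0.152), iron (6.92e-05, then 0.288), PAU (0.0016, then 0.514) and NAD and biotin (0.0432, then 0.152) lists had the lower effect, with 6, 4, 1 and 1 members lower and 1 NAD and biotin gene higher adjusted over the list alone, and no member of any of these 12 lists past the threshold over all probe sets. The mevalonate (0.383), marker (0.521), mating type alpha (0.52) and haploid mating (0.68) lists did not pass. Median, mean and test differed in sign in 10 lists in this comparison and in 10 between the media, none of which passed.

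Single arrays ended list calls in this comparison too, with the adjusted p without the array in parentheses. The array labelled Orange01 replicate 2 ended those of hexose transport (0.168), mating type a (0.142), PAU (0.079) and NAD and biotin (0.079). For mating type a the others were CEN.PK113-7D glucose replicates 1 and 2, glucose and ethanol replicate 3 and Orange02 replicate 3 (highest 0.11). NAD and biotin lost its call without CEN.PK113-7D glucose replicate 3 or 4, Orange01 replicate 1, glucose and ethanol replicate 2 or 3, or Orange02 replicate 1 or 3 (highest 0.126). Oxidative stress lost it without CEN.PK113-7D glucose replicate 4, Orange01 replicate 1, glucose and ethanol replicate 1 or Orange02 replicate 2 (highest 0.0994). The tricarboxylic acid cycle lost it without CEN.PK113-7D glucose replicate 4, Orange01 replicate 3 or Orange02 replicate 2 or 3 (highest 0.0706). Fatty acid genes lost it without CEN.PK113-7D glucose replicate 1, Orange01 replicate 3, glucose and ethanol replicate 1 or Orange02 replicate 2 (highest 0.153).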

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

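The tests of explanations in this part, the counts of other splits of the arrays included, were all chosen after the results they bear on were seen.

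The array labelled Orange01 replicate 2 had high galactose genes, and its BTS1 and PHO5 signals lay at the level of CEN.PK113-7D. A mixture holding at least 5% Orange01 RNA is argued against by BTS1, which gives a share of 0.689% (spread 0.509). A wrong label, with RNA of a CEN.PK113-7D culture grown on galactose, stays open. The description file of this array, which names CEN.PK113-7D and galactose, goes with a wrong label. So does URA1, which gave 362.3 on this array, inside the CEN.PK113-7D glucose range of 287.7 to 402.5. The other Orange01 arrays gave 1037 and 990.7 for URA1. Of the 28 probe sets that passed without this array, 26 are left without BTS1 and PHO5, which prompted this explanation. For 8, URA1 included, the array lay on the CEN.PK113-7D side of the midpoint, more than 2 prediction SE from the other Orange01 arrays. For 17 it lay on the Orange01 side, at any distance. Of these 17, 9 name 1 gene. The array shares its scanner type with the Orange01 arrays, so this count does not decide the label. An Orange01 culture on galactose without its BTS1 overexpression stays open too, because the URA3 signal of 101.9 lies inside the CEN.PK113-7D range of 38.9 to 123 and below the 183.8 and 192.9 of the other Orange01 arrays, a gap that galactose could also bring. The URA3 control probe set gave 242.1 on this array, next to the highest CEN.PK113-7D glucose value of 240.3 and below the 337.6 and 296.7 of the other Orange01 arrays, which does not decide it.

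The 11 gene lists that were lower in Orange01, with none higher, go with a trend of the log2 change with signal, from 0.17 in decile 3 to −0.12 in decile 10. None of these 11 passed with an estimated correlation. A signal-dependent difference in scale is argued against as the whole cause for 4 lists (beta-oxidation, mating type a, mating type alpha and PAU), which lay below the 5th percentile of 10000 lists matched for signal and kept their calls after quantile normalization. The matched lists held genes drawn at random, while the estimated correlation was 0.692 within PAU and 0.243 within mating type a. Mating type alpha and PAU lost their calls under median scaling. Mating type a lost its call after quantile normalization without the array labelled Orange01 replicate 2. The argument is therefore weaker for these lists than for beta-oxidation. For 5 lists (glycolysis, respiration, the tricarboxylic acid cycle, fatty acid and oxidative stress) such a difference in scale may be the cause, since they lay inside the matched lists and lost their calls. For the ribosomal protein list it cannot be told apart from a strain effect, because it lay below the matched lists but lost its call. The array labelled Orange01 replicate 2 alone is argued against as the cause of all 11 by the 7 lists that passed without it. It may be the cause for hexose transport, whose shift went from −0.361 to −0.0175 without it (adjusted p = 0.733), as HXT2, HXT6 and HXT7 gave 399.9, 495.5 and 373.9 on this array, below every other array. For oxidative stress, mating type a and mating type alpha, which lost their calls without it at shifts of −0.142, −0.334 and −0.41 (with it −0.123, −0.425 and −0.433), this cannot be told. The PAU list may rest on CEN.PK113-7D glucose replicate 4, since its shift went from −0.406 to −0.08 without that array (adjusted p = 0.511). Scanner type and a biological effect of the strain stay open, untested.

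Drug resistance genes were higher in Orange02. A signal-dependent difference in scale is argued against by a list shift of 0.744 after quantile normalization, and by a list mean of 0.76 where the highest of the 10000 lists matched for signal had 0.228. An effect of 1 array alone is argued against by the highest adjusted p without 1 of the 7 arrays, 7.2e-17, with shifts of 0.689 to 0.808. As a hypothesis, the rise may belong to the Orange02 cultures, though clone, culture batch, scanner type and run day were not tested. Scanner type and run day of the CEN.PK113-7D glucose and ethanol arrays were not used here.

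Other splits of the same arrays were fitted for each count. For Orange01, 2 of the 35 splits gave at least the real 29 probe sets, so chance is not excluded. The highest other split gave 174, with CEN.PK113-7D replicates 1 and 2 and Orange01 replicates 1 and 3 against the rest, which points to a structure of the samples beyond the strain. For its lists 1 of 35 splits, the real one, gave 11, the highest other 8, so no other split reached the count. With an estimated correlation none of the 11 lists passed. For Orange02, 1 of 35 splits gave 27 probe sets, the highest other 1, which argues against chance at 1 split in 35. Its count of 7 lists was reached by 8 of 35 splits, the highest other 9, so chance is not excluded for that count. Between the media, 1 of 35 splits gave 3000 probe sets, the highest other 8, which argues against chance at 1 split in 35. The 3 lists were reached by 21 of 35 splits, the highest other 7, so chance is not excluded. For the difference between the strain effects, 2 of 100 splits gave at least 6 probe sets, the highest other 7, and 2 of 100 gave at least 13 lists, the highest other 13. Both counts were rare among the splits, but another split reached each of them. None of these shares was corrected for the number of counts tried.

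In groups of 4 arrays, 13 of the 123 groups and measures tested held 1 array far from the other 3, where 1 in 20, or 6.15, arises by chance. The distance is given as the gap to the nearest array over the range of the group, on floored log2 signals for genes, and exceeded the 95% critical value of Dixon's test. CEN.PK113-7D glucose replicate 4 stood apart in the share of probe sets under 12 (29.9% against 27.3% to 27.6%, 0.872), the 3′ to 5′ ratio of ACT1 (2.6 against 1.74 to 1.83, 0.889), the spike-in control BioB (223.5 against 57.7 to 81.1, 0.858) and FAS1 (signal 5.2 against 420 to 612.7, 0.904). Glucose and ethanol replicate 2 stood apart in SNQ2 (7.99 against 370.3 to 470.6, 0.935) and SHU2 (11.2 against 68.5 to 87.1, 0.879). Replicate 1 of that group did so in a PDR5 probe set (15.8 against 9.39 to 12.3, 0.913) and ENO2 (3143 against 3364 to 3388, 0.905), and replicate 3 in CPS1 (140 against 103.7 to 107.3, 0.886). With the other 3 arrays at the floor, the ratio was 1 for CPD1 in CEN.PK113-7D glucose replicate 2 (signal 16.8) and for PSP2 (12.5), RDN18-1 (13.3) and NGK1 (12.4) in replicate 3.

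The effect of Orange02 differed from that of Orange01 in the limma test of the difference for UGA3 (log2 −1.49), RDN18-1 (−1.39), CPD1 (−1.99), HEM3 (−1.41), PSP2 (−1.02) and YGR035C (1.90), where the values of RDN18-1 and PSP2 restate the Orange01 effect because the floor sets that of Orange02. The value of YGR035C largely restates the Orange02 effect, because its signals in glucose lay near the floor. By camera the same difference shifted 13 lists against the other genes, of which 1, drug resistance, passed with an estimated correlation (adjusted p = 0.00884). Higher were drug resistance (0.681), oxidative stress (0.178), beta-oxidation (0.277), the tricarboxylic acid cycle (0.197), respiration (0.219), hexose transport (0.518), fatty acid (0.18), ribosomal protein (0.208) and mating type a (0.424). Lower were iron (−0.661), Gcn4 (−0.424), NAD and biotin (−0.225) and PAU (−0.715).

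Control probe sets that entered no comparison carried signal. The highest of 4 spike-in controls gave 3645 on CEN.PK113-7D glucose replicate 4, 4216 on glucose and ethanol replicate 1, and 2333, 6645 and 685.9 on Orange02 replicates 1, 2 and 3, while it stayed at or under 16.9 on the other 9 arrays. The URA3 control probe set gave at least 242.1 on the Orange01 arrays, its lowest value on the array labelled Orange01 replicate 2 and 296.7 the next, against 99.02 to 240.3 in CEN.PK113-7D, and at least 170.3 on the Orange02 arrays against 86.8 to 125.4.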

How the results depend on the processing

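The fits without the array labelled Orange01 replicate 2 combined with quantile normalization or with CEN.PK113-7D glucose replicate 4 left out, and those without it for Orange02 and for the media, were chosen after the data were seen. The other alternatives were planned. Leaving out that array alone was planned for Orange01 and for the difference as one of the single arrays left out in turn, while its use as a second fit throughout was chosen after the data were seen.

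For Orange01 the count of 29 probe sets became 12 with quantile normalization, 5 with median scaling, 2 with a pseudocount of 16, 5 with a filter at 30, 3 with the compared groups alone, 254 with array weights, 12 with the replicate block, 6 with run day as a random block (correlation 0.0964 over 10 arrays and 6 run days), 10 with a 2-fold minimum and 61 without that array and CEN.PK113-7D glucose replicate 4. With a floor of 30 it was again 29, 23 higher and 6 lower, but 5 of them were shared with the first 29. Its count of 11 lists became 7 with quantile normalization or median scaling and 0 with an estimated correlation or with fry, and 8 with fry in its mixed form. Of the 11 themselves, only beta-oxidation, mating type a, mating type alpha and PAU kept their calls with quantile normalization. In the mixed form of fry only beta-oxidation of the 11 passed. For every comparison, the lists counted under an alternative need not be those of the first count. For Orange02 the 27 became 15 with a floor of 30, 14 with no filter and 48 with array weights, and the 7 lists became 2 with an estimated correlation, 2 with fry and 9 with its mixed form. Between the media the 3000 became 747 with a 2-fold minimum, and the 3 lists became 0 with quantile normalization or an estimated correlation, 16 with fry and 31 with fry in its mixed form. For the difference the 6 became 1 with quantile normalization, median scaling, a pseudocount or the filter at 30, 10 with no filter, 39 with array weights and 3 with that array out and quantile normalization. Its 13 lists became 8, and 4 with that array out, with quantile normalization, 1 with an estimated correlation, 2 with fry and 5 with its mixed form. The cause was not tested, apart from the 2-fold minimum and the compared groups alone, which by construction call fewer or use fewer arrays.

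Under quantile normalization the shift of the glycolysis list in Orange01 reversed to 0.0877, and to 0.115 with that array also out, and that of hexose transport to 0.0499 with both. The ribosomal protein shift in the difference reversed to −0.0144 and −0.0394. For Orange01 the log2 change of PDR3 became −0.02113 with quantile normalization and −0.02314 with median scaling, and that of ERG9 −0.131 with median scaling and −0.1328 with the replicate block. For Orange02 that of HMG1 became 0.01098 with quantile normalization. The difference became 0.04094 for ERG9 with median scaling, and for ERG20 −0.02032 with array weights and −0.08043 without that array and CEN.PK113-7D glucose replicate 4. Leaving out 1 array at a time, signs changed within the ranges of PDR3 (−0.01754 to 0.3336) and ERG9 (−0.01654 to 0.1148) for Orange01, and of BTS1 (−0.336 to 0.08733), ERG9 (−0.3545 to 0.09809) and HMG1 (−0.1483 to 0.007519) for Orange02. They did so in those of SNQ2 between the media (−1.235 to 0.5296, where 0.5296 passed), and of ERG20 (−0.06521 to 0.1062) and ERG9 (−0.3935 to 0.05903) for the difference. The cause was not tested.

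Leaving out 1 array at a time gave 7 to 69 probe sets and 8 to 10 lists for Orange01, 12 to 28 and 7 to 9 for Orange02, 2600 to 3121 and 3 to 4 between the media, and 2 to 8 and 10 to 13 for the difference. Over all alternatives named probe sets kept direction and side of the threshold in 298, 376, 762 and 281 cases for Orange01, Orange02, the media and the difference, lost the call in 52, 53, 30 and 79, gained one in 9, 0, 3 and 4, and changed sign in 6, 8, 1 and 9, all for values that had not passed. List shifts kept both in 167, 127, 54 and 276 cases, lost the call in 50, 6, 6 and 60, and reversed in 3, 0, 0 and 2. Deviations of arrays with the same replicate number correlated at −0.128 to 0.105, so the replicate block pairs nothing measurable. Run day was not fitted for the other comparisons, since the description files of 4 arrays were not used here. In 5 cases with a floor of 30 both groups lay at the floor and gave no direction. Signals near the floor limit what can be seen: 26.4% to 29.9% of the probe sets of an array lay under 12.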

Other observations

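The tests of hypotheses in this part were all chosen after the results were seen, as were the genes it names.

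Between the media in CEN.PK113-7D, several genes of iron uptake and its control rose: FET3 by log2 1.86 (adjusted p = 0.000584), AFT1, the iron regulator, by 1.57 (7.44e-06), and TIS11, which lowers transcripts of iron-using proteins, 3.42-fold (log2 1.77, adjusted p = 0.000218), while HMX1, a haem oxygenase, fell by 1.03 (0.00384). The iron list as a whole did not pass (adjusted p = 0.607, 3 members higher and 3 lower). Among regulators of drug resistance, PDR1 rose by log2 1.13 (0.000179) and YRR1 by 1.32 (0.000922), in a list that did not pass (0.217). The zinc transporter genes ZRT2 and ZRT1 fell by 1.48 (0.000162) and 1.24 (0.00837), in a list with adjusted p of 0.518. In genes of growth on ethanol or acetate, SIP4, a regulator of gluconeogenesis, rose by 1.46 (7.34e-05), MDH2 by 1.00 (7.76e-05), FBP1 by 0.97 (0.000257) and ICL1, of the glyoxylate cycle, by 0.85 (3.91e-05), while CRC1, a carnitine carrier, fell by 1.03 (2.96e-05).

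In Orange02 other iron genes besides FET3 gave SIT1 −1.28 (adjusted p = 0.0843) and TIS11 −1.39 (0.0823), and TIS11 passed at 0.0351 when the array labelled Orange01 replicate 2 was left out. Biotin genes gave BIO5 −1.03 (0.0652) and BIO3 −0.86 (0.088), neither past the threshold. In Orange01, HIS5 and STR3, of histidine and sulfur amino acid metabolism, rose 1.78-fold and 1.75-fold (adjusted p = 0.0413 each), and did not pass without that array (0.0707 and 0.0878). Their signals on that array, 262.8 and 313.4, lay close to those of the other Orange01 arrays (275.9 and 317.9 for HIS5, 326.2 and 312.8 for STR3).

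URA1 and URA3 are targets of the regulator Ppr1, whose activation may have raised both in Orange02. The other targets argue against this: the larger log2 change of URA4 and URA10 was 0.12 (0.1218 before rounding), with upper 95% limits of 0.447 for URA4 and 0.301 for URA10, below 0.848, or 0.5 times the URA1 change. Extra copies of URA1 or URA3 were not tested.

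PHO5 could be higher in the Orange strains through a rise of the phosphate genes as a whole. Without the array labelled Orange01 replicate 2, the other 12 members had a median log2 change of −0.0407 (median absolute deviation 0.0783) in Orange02 against 1.63 for PHO5, and of 0.231 (0.448) in Orange01 against 2.65. In both, this argues against a rise of the other members as large as that of PHO5. In that fit the phosphate list had adjusted p of 0.0683 in Orange01 (shift 0.267, with 4 members higher and 1 lower adjusted over the list alone) and 0.98 in Orange02, and with all arrays 0.473 and 0.887. A smaller rise of the list in Orange01, with PHO5 as its strongest member, stays open, because PHO5 was chosen after its size was seen.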
